A study of Mus musculus with 2 samples.

How the data were processed

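Single-cell RNA sequencing of CD45-positive cells isolated from tumours was done on a 10x Genomics Chromium instrument, per the labels' protocols. The cells were a pool from 9 mice, marked with TotalSeq hashtag antibodies. The submitters' processing notes name Cell Ranger 3.1.0, Seurat and the mouse build mm10, without giving their roles or settings. The 4 files used here, as deposited by the authors, hold text only: a sheet of the 2 libraries, a sheet of the hashtags with their sequences and treatments, the list of cell barcodes and the list of features. The barcode list is described as filtered in its name, but the rule by which barcodes were called as cells is not given in the sources used here. A matrix of counts per cell was not analysed here.

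The tests planned for counts summed per mouse and cell type, and for cell type shares per mouse, were therefore not run, and no normalization, clustering, doublet removal or hashtag assignment was made. A hashtag was placed in a treatment group only as the hashtag sheet states it, after stray spaces in the group names had been removed. All 9 hashtags of that sheet were also features of the feature list.

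Hashtags were compared by the number of differing bases at matched positions. Barcodes were counted, split into sequence and well number, and searched for pairs that differ at 1 or 2 bases. Shares of bases have 95% Wilson intervals. The gene lists were fixed before the data were examined and were looked up by exact symbol. The planned rule for named genes called for genes that differ between treatments with an adjusted p-value. It selected none, because no test was run, and the genes named are members of the fixed lists, the sorting marker and the treatment targets. Ptprc and Cd274 are in no fixed list and were added afterwards, together with the genes whose symbols have several rows. Of the 31053 gene identifiers, 30934 (99.6%) matched a table of mouse gene names, which gave the same symbol for 30468 and another symbol for 466. Gene positions came from the RefSeq table of assembly GRCm38.p6, matched by symbol; mm10 is another name of GRCm38.

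The search for close pairs was tested on simulated data. In 18756 simulated barcodes with 800 planted pairs, it found 826 pairs above the mean of shuffled lists, against 26 with none planted. The planted pairs differed only within the first 7 bases, so recovery of pairs elsewhere in the barcode was not tested. The simulated barcodes were built from random sequences, with fewer different sequences at positions 10 to 16 than the 3521 observed. Fewer shuffles were used than for the observed list. The alternatives tried were other ways of counting barcodes, features, gene list members and hashtag distances, and base shares in each part of the sorted barcode list. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.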

Results

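The data came from immune cells of mouse ovarian tumours. CD45-positive cells, that is cells carrying the leukocyte common antigen encoded by Ptprc, were isolated from the fresh tumours of 9 C57BL/6 mice. The cells of each mouse were marked with a hashtag, an antibody that carries a short DNA tag, and were then pooled for droplet-based single-cell RNA sequencing. The pool gave 1 gene expression library and 1 hashtag library. The files used here name the cells, the genes and the hashtags, and hold no count of any gene or hashtag in any cell. No cell could therefore be assigned to a mouse, no depth per cell is known, and no expression level or cell type share was compared between the treatments.

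The 9 hashtags marked 3 treatments, with 3 hashtags each. In the first group, tumours of 2F8cis cells were treated with an antibody against PD-L1, the ligand encoded by Cd274 that restrains T cells through the receptor PD-1, encoded by Pdcd1. These tumours carried the hashtags MouseHTO-7 (GAGTCTGCCAGTATC), MouseHTO-10 (CCGATTGTAACAGAC) and MouseHTO-13 (CTACATTGCGATTTG). In the second group, 2F8cis cells were combined with CA-MSCs, carcinoma-associated mesenchymal stem cells, and the tumours received the same antibody. Their hashtags were MouseHTO-11 (GCTTACCGAATTAAC), MouseHTO-12 (CTGCAAATATAACGG) and MouseHTO-14 (CTTTCGCCAACTCTG). In the third group, tumours of 2F8cis cells with CA-MSCs received the antibody together with IPI-926, an inhibitor of the Hedgehog pathway that acts on Smoothened, encoded by Smo. Their hashtags were MouseHTO-8 (TATAGAACGCCAGGC), MouseHTO-9 (TGCCTATGAAACAAG) and MouseHTO-15 (CCCTCTCTGGATTCT). The antibody was given 3 times at intervals of 2 days from day 19 after tumour cell injection. IPI-926 was given daily for 2 weeks from day 14.

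The design allowed a comparison of tumours with and without CA-MSCs under the antibody, and a comparison with and without IPI-926 in tumours that contained CA-MSCs. The third group against the first differs in both factors. None of the 9 hashtags marked a tumour without the antibody, and none marked a 2F8cis tumour given IPI-926 in the absence of CA-MSCs. With 3 mice against 3, a value per mouse has 20 arrangements, so an exact two-sided permutation test could not fall below p = 0.10. None was run, because no value per mouse was held.

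Each hashtag sequence was 15 bases long, and the 36 pairs differed at 9 to 15 positions, with a median of 11. The smallest difference, 9 bases, was found in 5 pairs. It was also 9 bases among the 27 pairs that joined different treatments and among the 9 pairs within a treatment.

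The list of called cells held 19313 barcodes, each 16 bases long and each different from every other. All carried the same well number. No pair of barcodes differed at a single base. Each labelled sample was stated to contribute 2000 cells, which makes 18000 for the 9 mice, so the list amounted to 107.3% of the stated input. Divided evenly over the mice, it would correspond to 2146 barcodes per mouse. The actual share of each mouse is not known. Base use along the barcode was close to even. The highest share of any base at any position was 28.6% for C at position 6 (95% Wilson interval 27.9 to 29.2%), and the lowest was 22.6% for A at the same position (22.0 to 23.1%). These intervals cover counting error only. They treat the barcodes as independent draws, although barcodes come from a fixed list and are not replicates. They also do not allow for the shares having been picked as extremes.

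The genes that could be counted comprised 31053 mouse gene identifiers, beside the 9 hashtags. The gene of the sorting marker and those of the treatment targets each had 1 row. Ptprc (ENSMUSG00000026395) lies on chromosome 1 from 138062859 to 138175756 and Cd274 (ENSMUSG00000016496) on chromosome 19 from 29362107 to 29388095, in GRCm38. Pdcd1 (ENSMUSG00000026285) lies on chromosome 1 from 94038305 to 94052553. The Hedgehog list had 4 of 4 members. Smo (ENSMUSG00000001761) lies on chromosome 6 from 29735497 to 29761366. The receptor gene Ptch1 (ENSMUSG00000021466) lies on chromosome 13 from 63508328 to 63573460. The transcription factor gene Gli1 (ENSMUSG00000025407) lies on chromosome 10 from 127329882 to 127341579. Hhip (ENSMUSG00000064325), which encodes a Hedgehog-binding protein, lies on chromosome 8 from 79965850 to 80058060. These are gene spans, all annotated as protein coding.

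All 111 genes of the 28 lists that were fixed for this tissue had exactly 1 row each. The 9 pathway lists covered T cell effector genes such as Gzmb and Ifng, exhaustion genes such as Lag3 and Tigit, interferon-response genes such as Isg15 and Cxcl10, antigen presentation genes such as H2-Ab1, suppressive macrophage genes such as Arg1, the Ccr2 and Cx3cr1 axis, TGF-beta, Hedgehog and the immediate early genes Fos and Jun. The 19 cell type lists covered T, NK, B and plasma cells, macrophages, monocytes, neutrophils, dendritic cells and mast cells. They also included cells that the CD45 sort should remove, such as tumour epithelium (Epcam, Krt8), fibroblasts or mesenchymal stem cells (Col1a1, Dcn) and endothelium (Pecam1, Cdh5). Ccr2, Gzma and Mrc1 stood in 2 lists each. The presence of a row says only that a gene could be counted, not that it was expressed.

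The table also held 259 genes with symbols that begin like T cell receptor segments, 379 immunoglobulin variable, diversity or joining segments, and 13 mitochondrial genes. The T cell receptor count went by the start of the symbol, so it can include other genes, such as Tradd. In the whole gene table, 71 rows shared 35 symbols, so that a symbol alone did not name 1 row. The chemokine genes Ccl19, Ccl21a, Ccl21b, Ccl21c and Ccl27 were among them, with 2 rows each. Ccl19 and the Ccl21 genes encode ligands of Ccr7, a migratory dendritic cell marker that had 1 row. Il11ra2 had 3 rows. These genes were named after the table had been examined.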

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

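Some settings had nothing to act on and say nothing about stability. The list has 1 well number and 0 pairs of barcodes at 1 differing base, so removing either left the 19313 barcodes as they were. All 111 fixed-list genes matched by exact symbol, so ignoring letter case could add none. Counting distinct symbols in place of gene identifiers gave 31017 in place of 31053. The smallest separation of the hashtags, 9 bases, became 7 when insertions and deletions were allowed and 8 when reverse complements were included. By their definitions, these alternatives could lower the separation or leave it unchanged, but could not raise it. The share of C at barcode position 6, 28.6% over all barcodes, was 29.3% in the upper part of the alphabetically sorted list, split at its midpoint, and 27.8% in the lower part, and the cause was not tested. Other settings foreseen for gene tests and cell type shares (another normalization, no filter on low counts, leaving out each mouse, a stricter hashtag margin) were not run, because the files used here hold no counts. For the same reason, nothing can be said of depth per cell.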

Other observations

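The tests in this part were chosen after the values had been seen. The list of called cells was longer than the stated input by 1313 barcodes, although capture in droplets normally loses cells. The list carries 1 well number, so it does not join barcodes of separately numbered wells. That number cannot show whether several wells were processed under it, which stays open and was not tested. Beads listed under a pair of barcodes that differ at 2 bases do not account for the surplus. There were 1724 such pairs against a mean of 1653 (SD 40.0) in 1000 lists whose right parts were shuffled, an excess of 71 pairs where 1313 would be needed. Barcodes repeated by the shuffling were dropped, which left as few as 19242 in a shuffled list against 19313 observed. Shorter lists tend to hold fewer pairs, so the excess may be overstated. Whether the stated 2000 cells per sample were a nominal figure, and whether barcodes without an intact cell were called, stays open and was not tested. No biological explanation was tested.

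The barcodes themselves had a visible structure. Barcodes of 16 random bases would give 46.9 pairs that differ at 2 bases, against the 1724 observed. In 892 pairs both differences lay in positions 1 to 7, in 821 they lay in positions 10 to 16, in 11 they were at positions 8 and 9, and in 0 pairs they crossed these parts. Only 960 of 16384 possible sequences occurred in the first 7 bases, and only 4 of 16 possible pairs at positions 8 and 9. These 4 differ from each other at both bases, so no crossing pair could involve positions 8 and 9. Positions 10 to 16 were less restricted, with 3521 different sequences. Lists with shuffled right parts gave 1544 to 1795 pairs, a range that includes the observed 1724. Their pairs at positions 8 and 9 ranged from 1 to 18, with a mean of 7.9, against the 11 observed. Right parts were shuffled only among barcodes with the same bases at positions 8 and 9, and barcodes repeated by the shuffling were dropped. Apart from these drops, every shuffled list kept the observed parts and only changed which right part stood beside which left part. The number of pairs was thus within the range given by this restricted recombination of the observed parts. The comparison cannot decide whether the barcode code was built from separate parts. The boundaries of the parts were themselves read from the observed list.

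All 31053 gene identifiers were mouse genes, so a transcript of another species, or of a transgene without a mouse identifier, has no row of its own in the feature list.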
